A study of Drosophila melanogaster with 12 samples.

How the data were processed

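The series holds 12 Affymetrix Drosophila genome arrays of fruit flies (Drosophila melanogaster), with 3 arrays in each of 4 groups. The groups cross developmental stage (larva or adult) with genotype (wild type or knockdown of selenophosphate synthetase 2, gene symbol Sps2). Per the labels' protocols, the animals fed on a cornmeal and yeast diet, RNA was isolated with TRIzol and its integrity measured on a Bioanalyzer, and a 3' in vitro transcription kit was used to make biotin-labelled cRNA. Each array is labelled as a separate biological replicate. How the knockdown was made, which line served as wild type, the sex and age of the animals and the part of the body taken are not given in the sources used here.

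The deposited table holds 1 log2 value per probe set and array, made by the authors with MAS5, per the submitters' processing notes; the version is not given in the sources used here. That the values are log2 was taken from the values themselves: their linear form has a trimmed mean of 500.01 or 500.02 on every array, and the lowest value is 0. The authors' MAS5 step had thus scaled every array to a common trimmed mean before deposit. A scaling of this kind does not make the arrays' distributions equal, and detection calls were not used here. The median log2 value over the probe sets of an array averaged 6.44 in adult knockdown, 6.72 in adult wild type, 6.09 in larval knockdown and 6.01 in larval wild type. For arrays, precision is limited by their number, here 3 per group. There were 0 columns that could not be tied to a sample.

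Of 18952 probe sets in the table, 183 control probe sets were left out. A probe set was tested where its value was at or above the 40th percentile of its own array on at least 3 of the 12 arrays, which kept 12827 probe sets. Gene symbols came from the platform annotation, in which 13646 of the remaining 18769 probe sets have 1 symbol, 402 have several and 4721 have none. Probe sets with several symbols or none were tested and counted but not named. Entrez identifiers of 13543 of the probe sets with 1 symbol were found in the RefSeq gene table (Release 6 plus ISO1 MT), which changed 0 symbols. Where a gene had more than 1 probe set, the one with the highest mean over the 12 arrays stood for the gene, which gave 10425 genes. No genome sequence was used here, and no coordinates are given.

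All 12 arrays entered 1 linear model with a mean for each of the 4 groups, fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a variance trend), so that the groups shared 1 estimate of the spread with 8 residual degrees of freedom. The contrasts were adult knockdown against adult wild type, larval knockdown against larval wild type, the difference of those effects (adult minus larva), and adult wild type against larval wild type. P-values were adjusted by the Benjamini-Hochberg method over the probe sets of a contrast, and an adjusted p under 0.05 is a call. Log2 fold changes are knockdown minus wild type, or adult minus larva, and are given with limma's standard error (SE) and n = 3 arrays per group. Where the lower group's mean lay below the 40th percentile of its arrays, the fold is given as "at least", taken against that percentile (35.2 to 40.2 in linear signal). MAS5 values this low have little signal over background, and the log2 change there is uncertain in size.

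Gene lists were tested with camera (limma) on 1 probe set per gene at a preset inter-gene correlation of 0.01, for lists with at least 5 genes tested, and adjusted over lists and both knockdown contrasts together. The camera test asks whether a list moved relative to all other genes. The difference contrast was adjusted on its own. The same test with a correlation estimated for each list, and fry, which does not compare a list with other genes, were run as alternatives. Lists whose counts are given "adjusted over the list alone" had the Benjamini-Hochberg method applied within the list.

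The design, the 41 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes Sps2 and the selenoprotein machinery; in each knockdown contrast the 10 genes with the largest rise and the 10 with the largest fall among called genes with a symbol that is more than an annotation number, whose 3 arrays per group do not overlap and whose higher mean is at or above the median of the tested probe sets (8.13); up to 4 called members of each list with the smallest adjusted p, or the 4 with the smallest p as values where none was called; and 5 genes in each direction for the other contrasts. Left out of the lists were 6 genes that an older name or a name pattern had wrongly matched, and 11 of the 785 list entries could not be matched to a gene. Replicate numbers did not pair arrays of the 2 genotypes: the residuals of arrays with the same number correlated at r = -0.09 to 0.02, so no pairing was used.

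The fit was tested on simulated arrays drawn from the real stage means, with 67 of 12827 probe sets changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold. The spreads were those of each stage after moderation by eBayes, which draws the spread of each probe set towards the variance trend. The tested fit makes the same assumption about the spread, so real arrays may give a different share of false calls. In the simulated adult contrast, 46.3% of the probe sets changed 1.5-fold, 65.7% of those changed 2-fold and 89.4% of those changed 4-fold were recovered, and the shares in the simulated larval contrast were 53.7%, 61.2% and 83.3%. For the difference between stages they were 31.3%, 59.7% and 78.8%, and for the wild-type stage contrast 38.8%, 61.2% and 90.9%. False calls numbered 20 of 154 in the adult (13%), 72 of 204 in the larval (35.3%), 17 of 130 in the difference (13.1%) and 20 of 147 in the stage simulation (13.6%), all above the share of 0.05 that the adjustment aims at; with the 6 arrays of the stage alone they numbered 11 for adults and 15 for larvae. The shared spread thus gave more false calls than the arrays of the stage alone in both simulated knockdown contrasts, and far more in the larval one. Larval arrays varied more, but whether this was the reason was not tested. The median SD within a group was 0.11 and 0.10 in adult knockdown and wild type, and 0.17 and 0.18 in larval knockdown and wild type. In the list test, a 1.5-fold shift of 38 genes among 10425 was called in each of the 3 simulated contrasts, with 0 of 36 other lists called. The simulated genes varied independently of each other. This therefore does not test whether the preset correlation guards against false calls in lists whose genes vary together.

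The alternatives were quantile normalization, centring each array on its median, log2(signal + 32), no filter and a filter at the 60th percentile, no variance trend, array weights, the replicate number as a block, the 6 arrays of a stage alone, a 2-fold minimum, the mean of all probe sets of a gene, other list tests, and leaving out each array in turn.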

Results

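Transcript levels of fruit flies were measured on 12 Affymetrix Drosophila genome arrays, with cRNA made by a 3' in vitro transcription kit. Of these, 3 were of adult and 3 of larval flies with a knockdown of selenophosphate synthetase 2, and 3 were wild-type arrays at each stage. Selenophosphate synthetase 2, the product of Sps2, makes the selenium donor from which selenocysteine is built. The question, from the series title, was which transcripts differ when this enzyme is reduced. Within a group the arrays correlated closely (Spearman's rho across probe sets 0.993 to 0.994 in adult wild type and 0.983 to 0.984 in larval wild type), and between genotypes rho was 0.964 to 0.973 in adults and 0.958 to 0.965 in larvae.

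Sps2 itself was lower on every knockdown array than on any wild-type array. In adults it read 113.4 to 137.9 in linear signal with the knockdown and 878.4 to 919.6 in wild type, a 6.97-fold fall (log2 change -2.80, SE 0.12, n = 3 per group, limma adjusted p = 2.66e-08). In larvae the readings were 138.0 to 188.3 against 717.7 to 830.4, a 4.95-fold fall (log2 change -2.31, SE 0.12, adjusted p = 1.37e-07). The difference between stages was not called for any gene of the selenoprotein machinery.

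**Figure D1:**
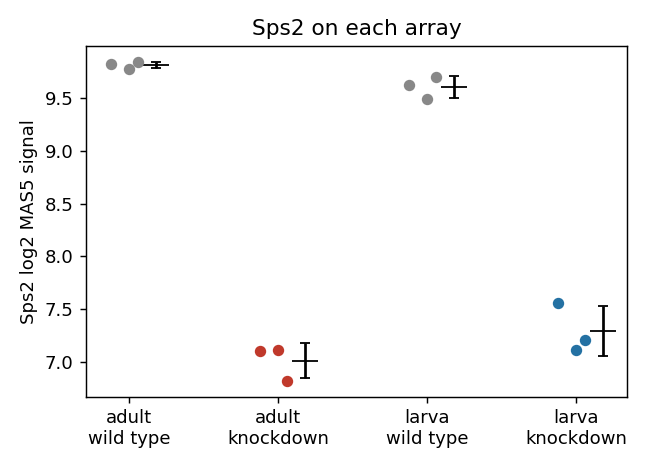
Log2 MAS5 signal of Sps2 on each of the 12 arrays (points, 3 per group), with the group mean and SD (bars). All 6 knockdown arrays lie below all 6 wild-type arrays, with group means of 7.01 and 9.81 in adults and 7.29 and 9.60 in larvae.

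Among the other 8 measured genes of the selenoprotein machinery, SelG and SelT fell at both stages. SelG, a selenoprotein of the endoplasmic reticulum, fell by 0.43 (SE 0.07) in adults and by 0.62 (SE 0.07) in larvae on the log2 scale, and SelT, whose fly form carries cysteine in place of selenocysteine, fell by 0.47 (SE 0.05) and by 0.53 (SE 0.05). SelR, a methionine sulfoxide reductase, rose in adults by a log2 change of 0.21 (SE 0.04, adjusted p = 0.00383), and read 0.13 (adjusted p = 0.0521) in larvae; its other probe set read 0.59 and 0.14. The selenoprotein BthD had log2 changes of 0.15 and 0.30 in adults and larvae, the elongation factor eEFSec 0.25 and 0.25, SecS -0.08 and 0.02, Sbp2 0.18 and -0.04 and Secp43 0.30 and 0.41, none of them called. As a list of 9 genes, 1 rose and 3 fell in adults, and 0 rose and 3 fell in larvae. Adjusted over the list alone, the counts were 1 and 3, and 3 and 3. The list includes Sps2 itself, the targeted gene, which is 1 of the 3 falls at each stage and pulls the means of the list down. The list did not differ from other genes in either contrast (camera adjusted p = 0.649 and 0.292); its medians were 0.15 and 0.02 and its means -0.30 and -0.27.

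Among genes that the naming rule allows, the adult knockdown was accompanied by higher LysX, a lysozyme, Prx6c, a peroxiredoxin, and Ser12, a serine protease. LysX was at least 24.34-fold higher (log2 change 7.50, SE 0.74, adjusted p = 1.63e-05), with 9.93 ± 1.35 in the knockdown and 2.43 ± 0.79 in wild type (log2 signal, SD, n = 3). Prx6c was at least 39.89-fold higher (log2 change 6.51, SE 0.46) and Ser12 at least 10.36-fold higher (5.49, SE 0.83). Eip63E, a cyclin-dependent kinase, was 27.3-fold higher (4.77, SE 0.11, adjusted p = 9.66e-11), and whd, the carnitine palmitoyltransferase of mitochondrial fatty acid import, was 11.3-fold higher (3.50, SE 0.21). Zip102B, of the ZIP family of metal transporters, and the carboxylesterase alpha-Est2 were at least 12.63-fold and at least 7.23-fold higher. Rbm13 rose 7.16-fold, Drep1 5.72-fold and Lsp2, a larval serum protein, 6.83-fold; the Lsp2 call (adjusted p = 0.0343) was lost when any 1 adult array was left out, with adjusted p up to 0.107, and with no variance trend or the replicate number as a block. Single arrays moved the size of some rises. LysX read 8.22 without adult knockdown replicate 1 and 6.89 without replicate 3. Ser12 read 4.77 without adult wild-type replicate 1 and 6.20 without replicate 3. Zip102B read 5.34 without adult wild-type replicate 1.

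Under the same rule the adult falls included Ugt35B1, a UDP-glycosyltransferase, and l(2)gl, the cell polarity gene lethal giant larvae. Ugt35B1 was at least 19.9-fold lower (log2 change -6.83, SE 0.49) and l(2)gl at least 32.86-fold lower (-5.64, SE 0.15, adjusted p = 2.17e-10). The odorant-binding protein gene Obp51a was 19.6-fold lower (-4.29, SE 0.70), mol, which encodes a maturation factor of the oxidase Duox, 17.9-fold lower (-4.17, SE 0.22), and Send2, a spermathecal endopeptidase, 13.7-fold lower (-3.78, SE 0.55; -4.40 without adult wild-type replicate 1). The cytochrome P450 genes Cyp12c1 and Cyp6a19 fell 8.46-fold and 7.59-fold, the translational regulator orb2 7.27-fold and otk2 7.13-fold.

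**Figure D2:**
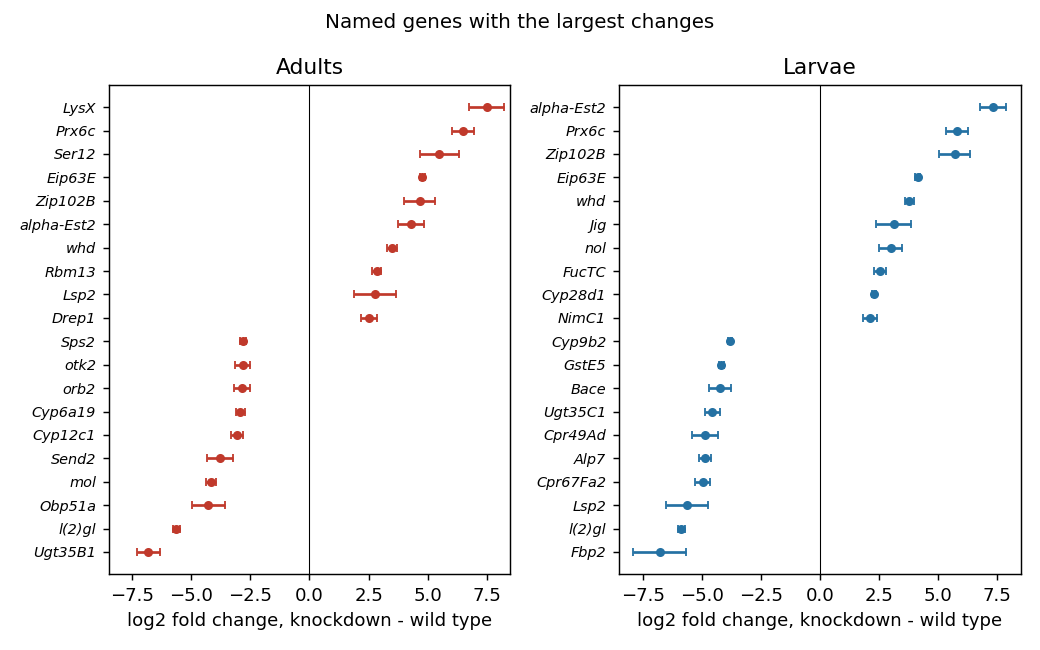
Log2 fold change (knockdown minus wild type, x axis) of the 10 genes with the largest rise and the 10 with the largest fall in adults (left) and larvae (right), among called genes with a symbol that is more than an annotation number, no overlap of the groups and a higher group mean at or above 8.13, with limma's SE as bars, n = 3 arrays per group. Prx6c, Eip63E, Zip102B, alpha-Est2 and whd are among the plotted rises at both stages, and l(2)gl is among the plotted falls at both, with -5.64 in adults and -5.87 in larvae.

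Among adult gene lists, genes of the cell cycle and DNA replication were higher in the knockdown: 13 of 23 rose and 0 fell (adjusted over the list alone, 17 and 0), with a median log2 change of 0.40 and camera adjusted p = 3.45e-07, against an adjusted p = 0.305 with an estimated correlation. Thymidylate synthase (Ts) rose 2.89-fold, the kinesin ncd 1.86-fold, the ribonucleotide reductase subunit RnrL 1.49-fold and PCNA 1.45-fold. Proteasome genes were also higher, with 17 of 38 up and 1 down (19 and 1 adjusted over the list alone) and a median of 0.13 beside a mean of -0.02 (adjusted p = 0.00153; adjusted p = 0.628 with an estimated correlation). Prosbeta6 rose 1.24-fold, Prosbeta2 1.22-fold and Prosbeta4 1.20-fold.

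Oxidative phosphorylation genes were lower in adult knockdown flies: 36 of 75 fell and 2 rose (38 and 2 adjusted over the list alone), with a median of -0.16 and adjusted p = 4.45e-06, against adjusted p = 0.628 with an estimated correlation. The complex I subunits ND-39, ND-SGDH and ND-18 fell 1.45-fold, 1.41-fold and 1.27-fold. In the same contrast 9 of 23 muscle structure genes fell and 0 rose (9 and 1 adjusted over the list alone). The muscle list was not called (adjusted p = 0.0613). Its adjusted p at the preset correlation ran from 0.0184 without adult knockdown replicate 3 to 0.203 with the mean of all probe sets. Of 19 neuronal markers 4 fell and 0 rose (3 and 0 adjusted over the list alone). The neuronal list was not called either (adjusted p = 0.0525), with a range from 0.0288 with the mean of all probe sets to 0.0731 without adult wild-type replicate 3. Of the testis markers, 17 of 34 fell and 0 rose (20 fell and 1 rose adjusted over the list alone), with a median of -0.55 (adjusted p = 0.00143; adjusted p = 0.628 with an estimated correlation); Mst87F fell 2.37-fold, mia 1.72-fold, djl 1.65-fold and Mst98Ca 1.54-fold. The male accessory gland markers had a median of -0.32 with 2 of 26 lower and 0 higher (0 and 0 adjusted over the list alone; list adjusted p = 0.419), and the female reproductive markers a median of -0.12 with 0 of 29 called by either adjustment (list adjusted p = 0.927). Malpighian tubule markers fell in 6 of 12 cases and rose in 0 by both adjustments (median -0.53, adjusted p = 0.0111; adjusted p = 0.305 with an estimated correlation), among them the transporters Oatp58Db, at least 5.25-fold lower, Picot, 2.11-fold lower, and Oatp58Dc, 1.82-fold lower.

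Cytochrome P450 genes as a list moved down in adults, with 27 of 75 lower and 9 higher by both adjustments and a median of -0.35 (adjusted p = 0.0349; adjusted p = 0.628 with an estimated correlation). Cyp6d5 fell 4.38-fold and Cyp4ac1 3.02-fold, while Cyp28d1 rose 4.68-fold. Odorant-binding proteins followed, with 10 of 39 lower and 1 higher by both adjustments (median -0.43, adjusted p = 0.0456; adjusted p = 0.628 with an estimated correlation); Obp99d was at least 3.15-fold, Obp49a 2.60-fold and Obp56a 2.01-fold lower. The P450 call did not hold under quantile normalization (adjusted p = 0.139), the stricter filter (0.0579) or without adult wild-type replicate 3 (0.0554). The odorant-binding call did not hold with no filter (0.0751), with no variance trend (0.0516), or without knockdown replicate 1 (0.0785), knockdown replicate 2 (0.0861) or wild-type replicate 2 (0.0559) of the adults, or without larval knockdown replicate 2 (0.0594).

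Over all tested probe sets, 3717 of 12827 (29.0%) were called in the adult contrast, 1742 higher and 1975 lower, of which 612 changed at least 2-fold (219 higher, 393 lower), and 5189 had an unadjusted p under 0.05. Groups did not overlap for 58.2% of the probe sets, where chance gives 10% if whole arrays do not differ. The median log2 value was lower on every adult knockdown array (6.37 to 6.48) than on any adult wild-type array (6.69 to 6.77). Such a difference can separate probe sets by itself, and the share was not computed under another scaling. Centring each array on its median turned the balance, to 2455 higher and 1596 lower, and without adult knockdown replicate 2 the number called higher was 1098. With the 6 adult arrays alone, which vary less than the larval ones, 6190 probe sets were called (2878 higher, 3312 lower).

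In larvae, the knockdown was accompanied by lower Fbp2 and Lsp2, which encode proteins of the larval fat body, and by lower transcripts of 2 cuticle protein genes. Fbp2 was at least 80.3-fold lower (log2 change -6.78, SE 1.11, adjusted p = 0.000834) and Lsp2 48.5-fold lower (-5.60, SE 0.89, adjusted p = 0.000652); wild-type larvae varied widely in both, with 11.58 ± 2.83 and 12.63 ± 2.46 (log2 signal, SD, n = 3). Without larval wild-type replicate 1, 2 or 3 the change of Fbp2 was -8.42, -6.06 or -5.88, and that of Lsp2 -7.02, -4.87 or -4.90. Cpr67Fa2 and Cpr49Ad, of the Cpr family of cuticle proteins, fell 30.9-fold (-4.95, SE 0.32) and 29.0-fold (-4.86, SE 0.56), and the alkaline phosphatase Alp7 fell 29.3-fold (-4.87, SE 0.25). The cuticle protein list as such went both ways, with 9 of 85 genes higher and 6 lower (5 and 5 adjusted over the list alone; camera adjusted p = 0.925). l(2)gl fell 58.7-fold (-5.87, SE 0.15, adjusted p = 2.64e-10). The UDP-glycosyltransferase gene Ugt35C1 fell 23.2-fold, the glutathione transferase gene GstE5 17.9-fold and the P450 gene Cyp9b2 13.9-fold. The aspartic protease gene Bace fell 18.6-fold (log2 change -4.22, and -3.43 without larval wild-type replicate 3).

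Larval rises among genes that the naming rule allows included alpha-Est2, at least 26.48-fold (log2 change 7.35, SE 0.55), Prx6c, 56.5-fold (5.82, SE 0.46), and Zip102B, at least 21.19-fold (5.72, SE 0.66). Eip63E rose 17.8-fold (4.15, SE 0.11) and whd 14-fold (3.80, SE 0.21). Further rises were those of Jig (8.82-fold), nol (8.05-fold), the fucosyltransferase gene FucTC (5.90-fold), Cyp28d1 (4.91-fold) and the hemocyte receptor gene NimC1 (4.39-fold); the Jig call was lost with array weights (adjusted p = 0.0519). Without larval wild-type replicate 1 the change of Jig was 2.45 in place of 3.14 and that of Zip102B 6.59. Without replicate 2 that of alpha-Est2 was 8.10.

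Among mitochondrial ribosomal protein genes in larvae, 46 of 69 rose and 3 fell (49 and 4 adjusted over the list alone), with a median log2 change of 0.31 and camera adjusted p = 4.71e-10, against adjusted p = 0.628 with an estimated correlation. mRpL48 rose 3.63-fold, mRpL20 1.73-fold and mRpL18 1.56-fold, while mRpL45 fell 1.85-fold. Cytosolic ribosomal protein genes rose in 9 of 41 cases and fell in 0 by both adjustments (median 0.09, adjusted p = 0.0101; adjusted p = 0.749 with an estimated correlation), a call lost under median centring (adjusted p = 0.119) and without larval knockdown replicate 3 (0.150). RpL7-like, which rose 1.31-fold, is named for its likeness to a ribosomal protein, and the list holds such genes too. Among the called members, RpLP0-like (log2 change 0.40) and RpL24-like (0.25) are also of this kind. With the 6 larval arrays alone, RpLP0-like (limma adjusted p = 0.0577), RpL24-like (0.0561) and RpS12 (log2 change 0.15, adjusted p = 0.115) lost their calls.

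Testis markers moved up in larvae, opposite to adults: 11 of 34 rose and 0 fell (12 and 0 adjusted over the list alone), with a median of 0.55 (adjusted p = 0.0101; adjusted p = 0.628 with an estimated correlation; 0.0509 without larval knockdown replicate 1). Among them ocn rose 1.86-fold, Mst84Db 1.78-fold and Mst84Dc 1.64-fold. The larval P450 list went down with 31 of 75 genes lower and 9 higher (35 and 10 adjusted over the list alone; median -0.40, adjusted p = 4.45e-06; adjusted p = 0.305 with an estimated correlation), including Cyp6d4 (3.67-fold) and Cyp28a5 (3.63-fold). Malpighian tubule markers fell in 5 of 12 cases and rose in 1 by both adjustments (median -0.25, adjusted p = 0.0475; adjusted p = 0.305 with an estimated correlation), with Oatp58Db at least 3.23-fold and ZnT35C 2.16-fold lower. The tubule call was lost under quantile normalization (0.0510), the stricter filter (0.109) and the block by replicate number (0.0718), without adult wild-type replicate 2 (0.0545), without larval knockdown replicate 2 (0.0594) and without larval wild-type replicate 2 (0.0676) or 3 (0.0541).

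**Figure D3:**
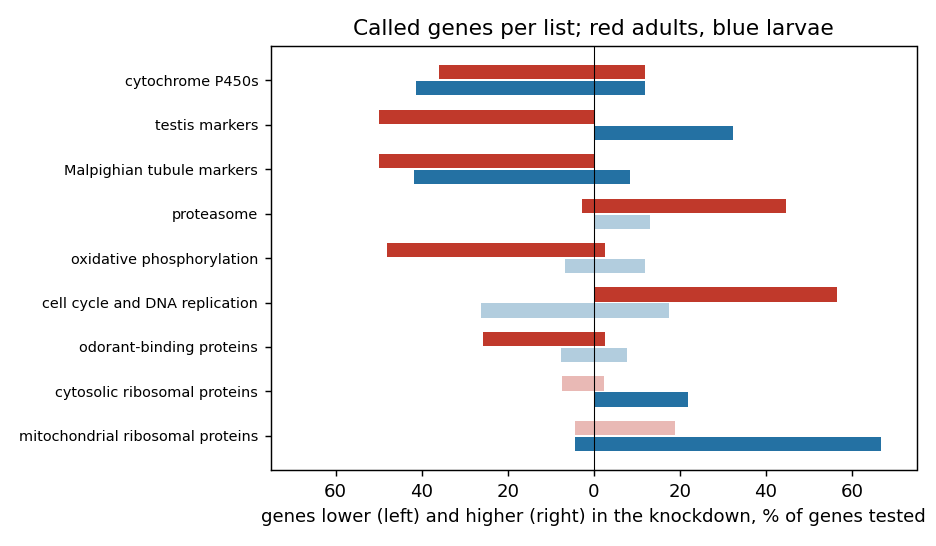
Genes called lower (bars to the left) and higher (bars to the right) in the knockdown, as a percentage of the tested genes of each list called by camera at either stage, adults in red and larvae in blue; pale bars mark a stage where the list was not called. Testis markers lie on opposite sides, with 17 of 34 lower in adults and 11 of 34 higher in larvae.

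The larval contrast called 3287 of 12827 probe sets (25.6%), 1918 higher and 1369 lower, with 726 changed at least 2-fold (405 higher, 321 lower) and 4723 at an unadjusted p under 0.05. The excess of rises depends on the scaling: the split was 1693 higher and 1417 lower under quantile normalization and 1602 and 1606 under median centring. Groups did not overlap for 35.4% of the probe sets, where chance gives 10% if whole arrays do not differ. The 6 larval arrays alone called 2235, with 1234 higher and 1001 lower. On simulated data 35.3% of the larval calls of the fit to all arrays were false. The simulation changed a far smaller share of the probe sets than was called here, so its false share does not carry over to these calls. The 3' minus 5' difference of the control transcripts, a sign of RNA quality or labelling, was 3.70 ± 0.06 in larval knockdown and 3.51 ± 0.11 in larval wild type (log2, SD, n = 3), against 2.44 ± 0.07 and 2.42 ± 0.07 in adults.

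Several genes changed by similar amounts at both stages. Of the 10425 genes tested, 1309 were called at both stages, and 1014 of these (77.5%) went in the same direction. Genes higher at both stages numbered 508, where independent lists would share 234.5, and genes lower at both numbered 506 against 184.9; those higher in adults and lower in larvae numbered 87 against 162.5, and those lower in adults and higher in larvae 208 against 266.9. Across all genes, which are not independent replicates, the adult and larval log2 fold changes correlated weakly (Pearson's r = 0.23, Spearman's rho = 0.13), and over the genes called at both stages r was 0.66. The 2 contrasts share no array, but they share 1 estimate of the spread for each probe set. A probe set with a low spread is thus more readily called in both, whatever the directions. The counts for independent lists are therefore a low standard for the overlap. Fitted changes of at least 4-fold at both stages were found for 43 genes, 39 of them in the same direction; they include Prx6c, Eip63E, Zip102B, alpha-Est2, whd and Cyp28d1 (higher) and l(2)gl, GstE5, Cyp12c1, Oatp58Db, Galphaq and Sps2 (lower). Galphaq, a G protein subunit of phototransduction, fell 4.05-fold in adults and 4.10-fold in larvae, while 1 of its other 2 probe sets was not called in either.

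**Figure D4:**
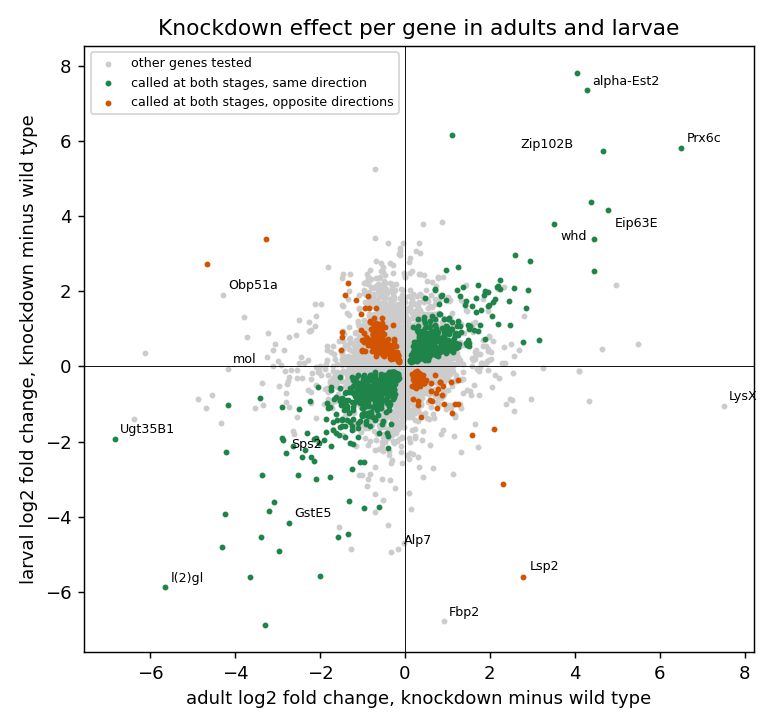
Adult (x axis) against larval (y axis) log2 fold change, knockdown minus wild type, for each of 10425 genes, with genes called at both stages coloured by whether the directions match. Points in the upper right and lower left, such as Prx6c and l(2)gl, moved alike, and Lsp2 lies in the lower right with 2.77 in adults and -5.60 in larvae.

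The test of the difference itself found a knockdown effect that differed between stages for 2665 probe sets, with 1009 more positive in adults and 1656 more negative. This split reads 1333 and 1436 under quantile normalization and 1726 and 1208 under median centring, so that its balance depends on the scaling. Genes named by the rule with a positive fitted difference were Lsp2 (8.37, SE 1.25, adjusted p = 0.00101), LysX (8.55, SE 1.05), Fbp2 (7.70, SE 1.57), Ser12 (4.89, SE 1.17) and Alp7 (4.73, SE 0.35). Those with a negative one were Obp51a (-6.20, SE 0.99), Send2 (-5.08, SE 0.77), Ugt35B1 (-4.91, SE 0.69), mol (-4.11, SE 0.31) and Hesr (-3.73, SE 0.91). All but Lsp2 and mol rest in part on group means below the 40th percentile of their arrays, where the size is uncertain. With such means set to that percentile the differences were 5.34 for LysX, 6.14 for Fbp2, 3.13 for Ser12 and 4.68 for Alp7. They were -4.38 for Obp51a, -3.87 for Send2, -3.32 for Ugt35B1 and -2.59 for Hesr. Leaving out 1 array moved several of the fitted differences by over 1.5 times, to 7.72 to 9.27 for LysX (without larval or adult knockdown replicate 1), 7.65 to 9.79 for Lsp2 (larval wild-type replicate 2 or 1) and 6.80 to 9.33 for Fbp2 (larval wild-type replicate 3 or 1). Those of Ser12 ran from 4.17 to 5.96 (without adult or larval wild-type replicate 1) and of Obp51a from -7.13 to -5.41 (larval wild-type replicate 3 or 2), while Send2 read -5.71 without adult wild-type replicate 1 and Hesr -4.52 without larval knockdown replicate 3. Without adult knockdown replicate 2 the count was 1887, with 680 more positive in adults.

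Of the gene lists, 7 of 37 differed between the stages by camera on the difference, and 0 with an estimated correlation. Cell cycle and DNA replication genes were more positive in adults (median difference 0.44, adjusted p = 4.93e-08; adjusted p = 0.113 with an estimated correlation). More negative in adults were the testis markers (-1.09, adjusted p = 3.01e-06; 0.414 with an estimated correlation), oxidative phosphorylation (-0.16, 2.97e-05; 0.590), mitochondrial ribosomal proteins (-0.26, 2.89e-05; 0.687), cytosolic ribosomal proteins (-0.12, 0.000668; 0.669), amino acid metabolism (-0.27, 0.0052; 0.369) and lipid metabolism (-0.24, 0.0236; 0.229).

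The genes given here for wild-type adults against wild-type larvae were picked by the naming rule. Gene lists were not tested in this contrast, so the picked genes do not show which kinds of gene differed. The accessory gland and seminal genes Acp98AB, Acp53C14b, EbpII, Acp53C14a and Mst57Da were at least 304.45-fold, 194.4-fold, 368.13-fold, 259.37-fold and 276.42-fold higher in adults. Higher in larvae were the cuticle protein genes Lcp65Ae, Cpr49Af and Cpr47Ec (at least 366.97-fold, 332.24-fold and 540.07-fold) and the salivary gland genes ng2 and ng1 (at least 449.29-fold and 334.49-fold). In all, 10486 probe sets (81.7%) were called, 6841 higher and 3645 lower in adults, with a median change of 0.51 over all tested probe sets. With arrays centred on their medians, 4277 were higher and 6104 lower, and under quantile normalization 5435 and 4633, so that the balance depends on the scaling. The hybridisation control spikes also differed, with a mean log2 signal of 10.30 ± 0.03 in adult and 11.17 ± 0.02 in larval wild type.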

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

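The tests of sex composition and age, the use of quantile normalization and of leaving out arrays (both fixed beforehand) to test these patterns, the differences with low group means set to the filter level, the tests on other probe sets of the same gene and the counts over other splits of the arrays were chosen after the results were seen; the test of chromosomal neighbours was set before its result was seen.

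The knockdown effect differed between adults and larvae for 2665 probe sets in the test of the difference itself. Among named genes the fitted difference of log2 fold changes (adult minus larva) was 8.55 for LysX, 8.37 for Lsp2, 7.70 for Fbp2, 4.89 for Ser12 and 4.73 for Alp7, and -3.73 for Hesr, -4.11 for mol, -4.91 for Ugt35B1, -5.08 for Send2 and -6.20 for Obp51a. With group means below the 40th percentile of their arrays set to it, Lsp2 and mol were unaffected. The others read 5.34 for LysX, 6.14 for Fbp2, 3.13 for Ser12, 4.68 for Alp7, -2.59 for Hesr, -3.32 for Ugt35B1, -3.87 for Send2 and -4.38 for Obp51a. A further 15 named genes were called in opposite directions at the stages. The difference was 3.39 for tobi, 1.86 for PPO1, 1.23 for Lcp65Aa and 0.70 for Ugt316A1. It was -2.48 for Pepck2, -1.83 for Obp83cd, -1.44 for ocn, -1.37 for Mst84Db, -1.26 for Mst84Dc, -1.24 for djl and -1.23 for TrxT. It was -1 for GstE9, -0.81 for Tps1, -0.49 for PCB and -0.27 for Idh. Both adult means of Lcp65Aa lay below that percentile. The larval calls of djl (adjusted p = 0.171) and Idh (0.1) were lost with the 6 larval arrays alone. That of Idh was also lost under median centring (0.117), with no variance trend (0.08) and with array weights (0.0596). With the mean of all probe sets of a gene, GstE9 in larvae (-0.52, adjusted p = 0.124) and PCB in adults (0.02, 0.898) turned in sign and were not called, and PCB in larvae lost its call (0.0753). The adult call of PCB was also lost under median centring (0.118). Without 1 array the difference ran from 7.72 to 9.27 for LysX, 7.65 to 9.79 for Lsp2, 6.80 to 9.33 for Fbp2, 4.17 to 5.96 for Ser12 and -7.13 to -5.41 for Obp51a, and reached -5.71 for Send2 and -4.52 for Hesr (the arrays are named beside these genes above). For gene lists the median difference was 0.44 for cell cycle and DNA replication, -1.09 for testis markers, -0.27 for amino acid metabolism, -0.26 for mitochondrial ribosomal proteins, -0.24 for lipid metabolism, -0.16 for oxidative phosphorylation and -0.12 for cytosolic ribosomal proteins. With an estimated correlation, 0 lists were called for the difference.

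For the difference, 2 of 100 splits of the arrays, the real one included, gave as many probe sets. This does not test whether the effects differ, since all but these 2 mix knockdown and wild type within a group, which raises the spread in any case. The other split called 3944 against 2665. It exchanges the genotype labels of all larval arrays and so tests the sum of the adult and larval effects, for which the count is also 3944: a structure of the samples. For the adult, larval and wild-type stage contrasts, 1 of 10 splits each, the real one, gave as many, and 10 splits are too few for a share under 0.05. The real and the highest other counts were 3717 and 7 in adults, 3287 and 14 in larvae, and 10486 and 1 between stages.

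A first pattern was the set of 1014 genes called in the same direction at both stages. The series has 1 knockdown and 1 wild-type genotype, and whether the lines share a background is not given in the sources used here. A sequence difference under single probe sets may account for part of it: in the 65 genes with another tested probe set, the other probe set changed by a median of 0.09 times the chosen one (95% bootstrap interval -0.19 to 0.30), against 0.80 (0.45 to 0.98) for the wild-type stage difference. The chosen probe sets were picked for being called in these contrasts and the others were not, which by itself lowers the first ratio. The genes were not picked on the stage difference in this way. Those 65 genes are also too few of the 1014 to decide, and of the 39 genes with a fitted change of at least 4-fold alike 2 had another probe set (median ratio 0.42). Neighbouring genes in the annotation (Release 6 plus ISO1 MT) shared the pattern 1.76 times as often as chance (95% interval 1.40 to 2.17). The ratio was 1.27 (1.11 to 1.46) for genes called in adults alone and 1.17 (0.97 to 1.38) in larvae alone. The first interval overlaps that for adults alone but not that for larvae alone. The rule set beforehand asked for an interval above both and was not met, though overlap is not a test of the difference. Stretches that differ between the lines and an effect of the knockdown thus cannot be told apart.

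A second pattern was the testis markers, lower in adults (median -0.55, 95% bootstrap interval -0.67 to -0.47) and higher in larvae (0.55, 0.43 to 0.70). The bootstrap intervals in this section resample genes, as if independent, and not arrays. They do not measure the spread between the samples of a group. Under quantile normalization the largest adjusted p of the list at either stage was 0.00815, which argues against the scaling as the whole source of these calls. The calls themselves rest on the preset correlation (adjusted p = 0.628 in adults and 0.628 in larvae with an estimated correlation), and the larval call was lost without larval knockdown replicate 1 (0.0509). A smaller share of males among the adult knockdown flies could give lower testis and accessory gland markers (-0.32, -0.50 to -0.25) and would raise female markers, whose median was -0.12 (-0.22 to 0.06): this does not decide, and the sex of the animals is not given in the sources used here. The dosage compensation and sex markers do not decide either. In adults their median was 0.12, with 1 of 5 genes higher and 0 lower (list camera adjusted p = 0.431). The spermathecal gene Send2, named above, fell in adults, but it was picked for its large change. An effect of the knockdown on the testis stays open and was not tested.

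The last pattern was the low Lsp2 and Fbp2 in larvae. A single array as the source of the call was argued against. Without any 1 of the 12 arrays, the largest limma adjusted p of either gene was 0.00506. The changes still ran from -8.42 to -5.88 for Fbp2 and from -7.02 to -4.87 for Lsp2 (without wild-type replicate 1, and without replicate 3 or 2). Larval wild-type replicate 1 read 9.78 for Lsp2 and 8.32 for Fbp2 in log2 signal. These values lay below the other larval wild-type replicates (14.08 and 14.02 for Lsp2, 13.03 and 13.39 for Fbp2) and above every larval knockdown array. Younger larvae in the knockdown samples may account for the pattern: the ecdysone response and timing list had a median of -0.41 (95% bootstrap interval -0.70 to -0.08), but its camera adjusted p was 0.0727, which leaves this open. A slower development caused by the knockdown would look the same, and was not tested.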

How the results depend on the processing

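No alternative reported here was chosen after the results were seen. Of 313 named gene results, 301 kept direction and call under quantile normalization, 305 under median centring and 302 with array weights; with the 6 arrays of a stage alone, which give no contrast between stages, 271 of the results that could be tested did and 22 lost their call. Under the mean of all probe sets of a gene, 302 kept both, 8 lost the call and 3 turned in sign: ScsbetaG (-0.02, adjusted p = 0.923) and PCB (0.02, 0.898) in adults and GstE9 (-0.52, 0.124) in larvae, whose other probe sets move differently. The change of Sps2 ranged from -2.85 to -2.71 in adults and from -2.44 to -2.22 in larvae when 1 array was left out. Values near the lowest signals have little signal over background, which limits the size of their log2 changes. The cause of the moves below was not tested, unless the alternative itself gives it.

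Under median centring, 1726 probe sets had a more positive effect in adults, and 4277 were higher and 6104 lower in adult than larval wild type. The correlation of effects between stages was 0.30 with log2(signal + 32), 0.18 with no filter and 0.31 with the stricter filter. Array weights called 5778 in adults (2756 higher, 3022 lower). The 6 arrays of the stage alone called 6190 (2878, 3312) in adults and 1234 higher in larvae. A minimum of 2-fold, a stricter criterion by construction, left 612 (219, 393) in adults, 726 (405, 321) in larvae, 937 (209, 728) for the difference and 6971 between stages (2207 lower). Lists called in larvae numbered 8 with no filter and 9 with the mean of probe sets; an estimated correlation gave 0 in adults and 0 in larvae, and fry 23 and 18. With the replicate number as a block, 3181 were called in adults, 2817 in larvae and 2131 for the difference. Leaving out 1 array gave 1098 (without adult knockdown replicate 2) to 1875 (without larval wild-type replicate 1) higher in adults, 2483 to 3980 called in adults, 2855 to 3183 in larvae and 1887 to 2814 for the difference.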

Other observations

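No test reported here was chosen after the results were seen. Single genes of lists that were not called also changed. In larvae the antimicrobial peptide genes BomBc2 and BomS2 fell, BomS2 at least 8.64-fold (log2 change -3.40, SE 0.31, n = 3 per group, limma), while the list as a whole had 5 of 25 genes higher and 4 lower (5 and 4 adjusted over the list alone; camera adjusted p = 0.594). The lysozyme LysP fell in larvae, at least 5.54-fold, and 1.52-fold in adults. The metallothionein MtnB rose 5.41-fold in adults and 3.35-fold in larvae, MtnC rose 1.82-fold and 1.60-fold, and MtnA fell 1.21-fold and 1.83-fold; of 17 metal-handling genes 4 rose and 3 fell at each stage, by both adjustments (camera adjusted p = 0.292 and 0.925).

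Among glutathione transferases, GstE5 fell 6.59-fold in adults and 17.9-fold in larvae and GstD2 fell 6.38-fold in larvae, while GstD5 was at least 2.58-fold higher in adults. Of 33 genes 5 rose and 6 fell in adults (7 and 6 adjusted over the list alone; camera adjusted p = 0.925), and 6 rose and 9 fell in larvae (7 and 9; 0.102). Among hemocyte markers NimC1 rose at both stages, while Hml (1.91-fold) and eater (2.57-fold) fell in adults. In adults 2 of 16 rose and 6 fell (2 and 7 adjusted over the list alone, camera adjusted p = 0.0723). The adult camera adjusted p ran from 0.0437 without adult knockdown replicate 2 to 0.151 with array weights. In larvae 4 of 16 rose and 4 fell (5 and 4 adjusted over the list alone, camera adjusted p = 0.761).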
